A study of Mus musculus with 8 samples.

How the data were processed

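Poly(A)-selected RNA was sequenced in paired-end libraries from mouse cells labelled pre-HSC (3 libraries, embryonic day 11.5), ex-HSC (3 libraries, stage given as in vitro) and FL-HSC (2 libraries, embryonic day 14.5), all on a C57BL/6J background. HSC stands for hematopoietic stem cell and FL for fetal liver. The labels' protocols describe a culture of 4 days in which sorted embryonic cells were reaggregated with OP9 stromal cells, a mouse bone marrow line, in medium with the cytokines SCF, IL-3 and Flt3L. The ex-HSC libraries were read as cells sorted from that culture, since their stage is in vitro. Cells were sorted into Trizol-LS, and DNase treatment was done by either of 2 methods, per the labels' protocols. The labels give neither the sort gates, nor which library had which DNase treatment, nor whether replicates came from separate litters or cultures.

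The authors deposited 1 table with 1 value per gene and library in FPKM (fragments per kilobase of transcript, scaled to the library's mapped fragments), per the file headers. Per the submitters' processing notes, Cufflinks, featureCounts, edgeR and DESeq were used with the mouse genome build mm9. The notes give no versions and do not say which tool made which value, so the deposited FPKM were used as they stand. The table has 33531 rows, of which 27 bear dates in place of gene symbols and were left out, which left 33504 genes, 7392 of them at 0 in every library. The table holds no counts, so read depth is unknown and no count model was run. As a rough guide to relative depth, values between 0 and 0.5 FPKM were divided by those of the same genes in pre-HSC replicate 1, and the most frequent log2 ratio was taken. The depth it implies, relative to pre-HSC replicate 1, was between 0.688 and 0.959, but at most 3.13% of the compared genes sat at that ratio, so whole reads were not recovered and no result rests on it.

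Values were transformed to log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 of the 8 libraries were tested, 13720 in all. One linear model with a mean per group was fitted to the 8 libraries in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and an intensity trend, and the 3 comparisons were taken from it. The limma p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The words rose, fell and changed are used only of called genes. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. Group values are mean FPKM ± SD over the 3 pre-HSC, 3 ex-HSC or 2 FL-HSC libraries, and log2 fold changes are given ± SE. Because the origin of the replicates is not stated, p-values measure only the spread between these libraries.

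An FPKM of exactly 0 can be a failed estimate. In 49 cases a gene was at 0 in 1 library and at 10 FPKM or more in every other library of its group, among them the widely used genes Ddb1, Prpf8 and Trp53. Genes at 0 are therefore described as listed at 0, with each library's value in place of a mean. Genes that share sequence with close copies, such as histocompatibility, Ifitm, Stfa, tryptase, hemoglobin and Csf2rb genes and processed pseudogenes, have values that depend on how shared reads were assigned, which is not stated.

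Before the data were examined, 27 gene lists were written, along with the comparisons, the tests, the alternatives and the rule for naming genes. Each list was tested with camera from limma at a preset correlation of 0.01 between genes, and again with a correlation estimated per list, with Benjamini-Hochberg adjustment over the 27 lists. Counts of called list members are given from the adjustment over all genes tested and from the adjustment over the list alone. These counts are of the members tested only, for example 13 of 25 lymphoid and 12 of 19 hepatocyte markers. Genes named in each comparison were Cd274, Pdcd1, Pdcd1lg2 and Ly6a, the 10 largest called changes in each direction, and up to 4 called members of each list with the largest changes. The 10 largest had a mean of at least 5 FPKM in the higher group and no overlap between the groups' libraries, and symbols of predicted or non-coding genes were left out. A further 10 per direction were the genes with the largest changes in the same direction in both comparisons against pre-HSC.

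Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, array weights, limma without the trend, a replicate block, fits of 2 groups only, a minimum absolute log2 fold change of 1, and each library left out in turn. The treatment of isolated zeros as missing values, and median-of-ratios scaling without ex-HSC replicate 2, were added after the data were seen. The shared changes of both comparisons against pre-HSC were set beside 100 simulated draws. In each draw all 8 libraries were simulated around the pre-HSC mean with each gene's spread, each gene independently. Both unchanged groups were then compared with the same 3 simulated pre-HSC libraries.

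The testing steps were first run on simulated data with 200 genes changed by known amounts. For ex-HSC against pre-HSC, with 12976 genes run, 0% of 67 genes changed 1.5-fold, 28.4% of 67 changed 2-fold and 83.3% of 66 changed 4-fold were called in the right direction, with 3 false calls. For FL-HSC against pre-HSC, with 12984 genes run, the shares were 1.49%, 14.9% and 84.8% for the same fold sizes, with 6 false calls. For FL-HSC against ex-HSC, with 12967 genes run, they were 0%, 7.46% and 84.8%, with 1 false call. Only 200 genes were changed in each run, so the adjustment was stricter than in the real comparisons, where many more genes were called. The shares therefore do not give the sensitivity of those comparisons. A simulated list shifted by 1 on the log2 scale, run on 13720 genes, was called by camera in all 3 comparisons with the preset and with the estimated correlation, and 0 of 20 unshifted lists were called. Simulated genes were drawn independently, whereas the correlations estimated within the real lists were 0.12 to 0.81. The run therefore does not show false calls or power for correlated genes. Gene positions were taken from GENCODE M21 on build GRCm38, since the table gives symbols without positions and no annotation of mm9 was at hand. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.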

Results

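RNA abundance was measured in 8 libraries of mouse blood stem cell populations. Pre-HSCs are precursors that arise from the endothelium of the embryo's large arteries and do not yet engraft adult recipients. Ex-HSCs came from 4 days of culture, and FL-HSCs came from the fetal liver, where stem cells expand after they leave the arteries. Between 11682 and 12757 genes per library had 1 FPKM or more. Between 15622 and 18374 genes were above 0 in 7 libraries, and 24992 were in ex-HSC replicate 2, of which 13310 lay below 1 FPKM. The sum of FPKM per library was between 553227 and 745619.

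**Figure D1:**
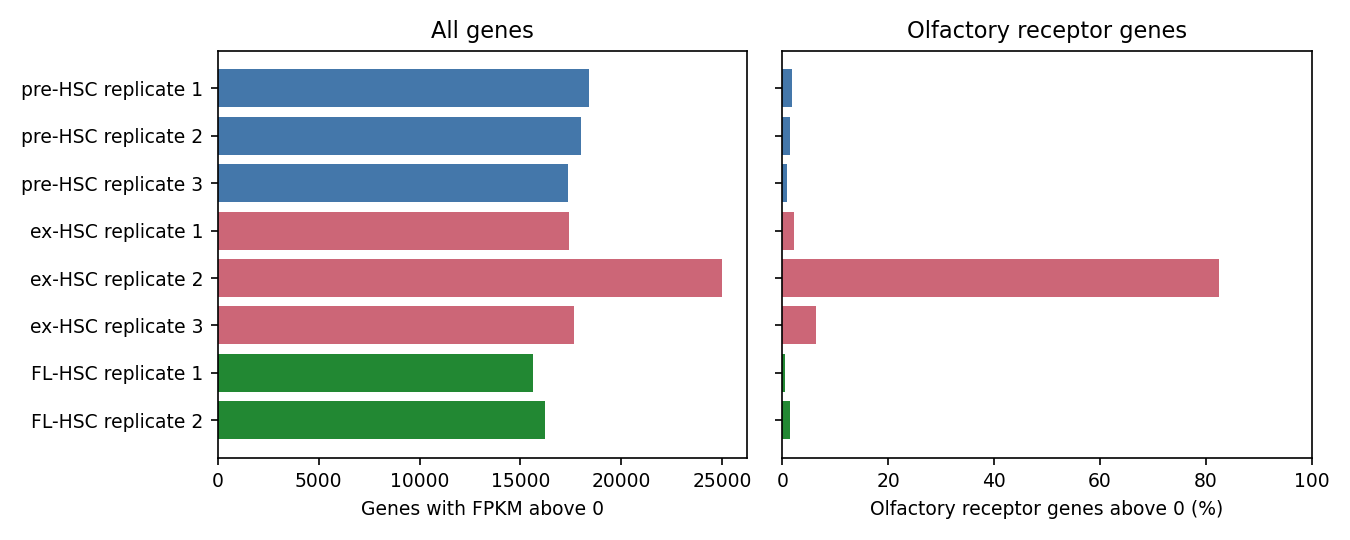
Number of genes above 0 FPKM (left panel, x axis) and percent of 1072 olfactory receptor genes above 0 (right panel, x axis) with the 8 libraries on the y axis. Ex-HSC replicate 2 has 24992 genes and 82.5% of olfactory receptor genes above 0, where the other libraries have at most 18374 genes and 6.44%.

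The libraries grouped by population. The first principal component of the 13720 tested genes held 56.3% of the variance and set the pre-HSC libraries apart from the others, and the second held 25.9% and set FL-HSC apart from ex-HSC. Across genes, which are not independent replicates, Pearson's r was 0.957 to 0.970 between pre-HSC libraries, 0.968 to 0.976 between ex-HSC libraries and 0.960 between the FL-HSC libraries. It was 0.861 to 0.891 between ex-HSC and FL-HSC libraries, 0.782 to 0.812 between pre-HSC and ex-HSC, and 0.798 to 0.818 between pre-HSC and FL-HSC.

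**Figure D2:**
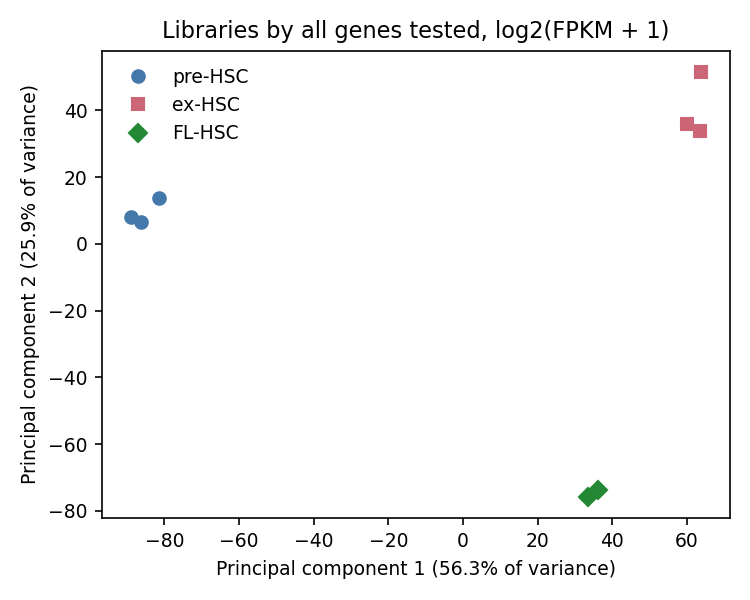
Principal components of log2(FPKM + 1) over 13720 genes, with 1 point per library coloured by population, the first component (56.3% of the variance) on the x axis and the second (25.9%) on the y axis. The 3 pre-HSC libraries lie together on the left, and ex-HSC and FL-HSC libraries part along the y axis.

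The series asks how the PD-1 ligand PD-L1 behaves as HSCs mature, so the genes of PD-1 and its ligands came first. Cd274, the gene of PD-L1 (chromosome 19, 29367455 to 29388095, plus strand, GRCm38), was low in pre-HSC and higher in both later populations. Its FPKM were 1.07, 1.35 and 1.15 in pre-HSC, 11.2, 4.29 and 6.82 in ex-HSC and 5.07 and 7.02 in FL-HSC, with means of 1.19 ± 0.142, 7.43 ± 3.49 and 6.05 ± 1.38. Cd274 rose in ex-HSC (6.26-fold, log2 fold change 1.86 ± 0.29, limma adjusted p = 0.000347) and in FL-HSC (5.09-fold, 1.68 ± 0.32, adjusted p = 0.00181) against pre-HSC. Cd274 did not pass between FL-HSC and ex-HSC (-0.19 ± 0.32, adjusted p = 0.690), and its sign there turned to 0.12 without ex-HSC replicate 1 and to 0.011 without FL-HSC replicate 1. The difference was larger, at -0.49 with median-of-ratios scaling, -0.46 with quantile normalization and -0.48 without ex-HSC replicate 2. With that library left out and median-of-ratios scaling it was -0.66, and Cd274 passed in none of these settings. In ex-HSC, Cd274 was highest in replicate 1, as were 43.1% of all genes that rose and all 15 mast cell markers that rose, and how much of it comes from mast cells in these libraries was not tested.

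Pdcd1lg2, the gene of the second PD-1 ligand PD-L2 (chromosome 19, 29410919 to 29471161, plus strand), lies next to Cd274. It was nearly silent in pre-HSC at 0.0896 ± 0.0578 FPKM, and rose to 7.16 ± 2.93 in ex-HSC (log2 fold change 2.84 ± 0.26, limma adjusted p = 6.14e-06) and to 2.69 ± 0.205 in FL-HSC (1.76 ± 0.29, adjusted p = 0.000630). Pdcd1lg2 was lower in FL-HSC than in ex-HSC (-1.08 ± 0.29, adjusted p = 0.0154). The log2 fold change was -1.14 without FL-HSC replicate 1 and -1.03 without FL-HSC replicate 2. The call was lost in each of these fits, where 1 FL-HSC library was left. Pdcd1, the gene of the receptor PD-1 itself (chromosome 1, 94038305 to 94052553, minus strand), was listed at 0, 0.140 and 0 FPKM in pre-HSC and at 0 and 0 in FL-HSC, against 9.35, 6.68 and 6.02 in ex-HSC. It rose in ex-HSC against pre-HSC (log2 fold change 2.98 ± 0.21, adjusted p = 8.09e-07) and was lower in FL-HSC than in ex-HSC (-3.04 ± 0.23, adjusted p = 1.05e-05). It did not pass between FL-HSC and pre-HSC (-0.06 ± 0.23, adjusted p = 0.847). Ly6a, which encodes the stem cell surface protein Sca-1 (chromosome 15, 74994877 to 74998031, minus strand), followed a different course from Cd274. It stood at 5.83 ± 1.96 FPKM in pre-HSC, 127 ± 33 in ex-HSC and 6.95 ± 4.30 in FL-HSC, and against pre-HSC it rose in ex-HSC only (log2 fold change 4.24 ± 0.34, adjusted p = 2.49e-06). It did not pass in FL-HSC against pre-HSC (0.15 ± 0.38, adjusted p = 0.776), where its sign turned to -0.011 with median-of-ratios scaling, to -0.12 without pre-HSC replicate 3 and to -0.43 without FL-HSC replicate 2. Against ex-HSC it was lower in FL-HSC (-4.09 ± 0.38, adjusted p = 3.78e-05). The proteins of Ly6a, Slamf1, Procr and Cdh5 are markers by which such cells can be sorted, and the gates are not given, so the values of these genes do not separate sorting from regulation.

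**Figure D3:**
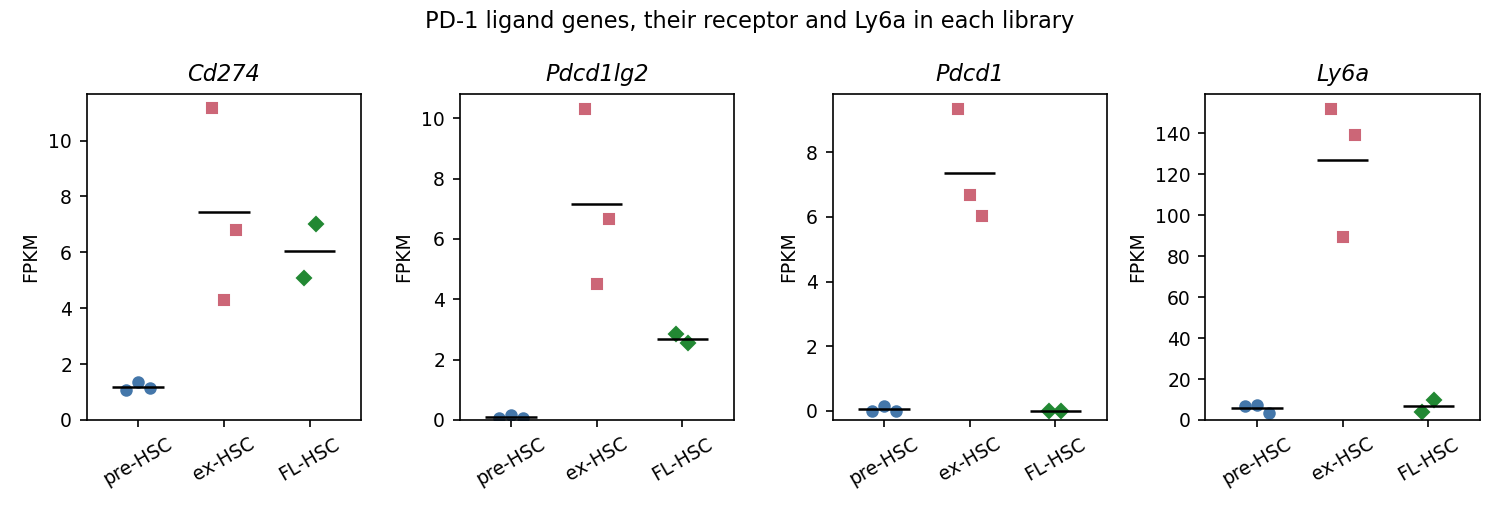
FPKM on the y axis for Cd274, Pdcd1lg2, Pdcd1 and Ly6a, with 1 point per library, the population on the x axis and a bar at the group mean. Cd274 lies between 4.29 and 11.2 FPKM in ex-HSC and at 5.07 and 7.02 in FL-HSC, against at most 1.35 in pre-HSC, while Pdcd1 is above 1 FPKM in ex-HSC libraries only.

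Gene lists chosen before the files were read showed what changed in the cultured ex-HSCs against pre-HSCs. All 32 endothelial genes fell, as did nearly all stromal genes and most imprinted genes. In pre-HSC, 32 of 32 endothelial and 25 of 26 stromal markers had a mean of at least 1 FPKM. Whether endothelial or stromal cells in the pre-HSC libraries gave these values was not tested. Most of the granulocyte, mast cell and lymphoid genes tested rose, as did most antigen presentation and amino acid stress genes and 14 of 27 checkpoint genes. Genes that mark stem cells did not move together.

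Vascular genes had the lowest median of the 27 lists in ex-HSC. Of 32 endothelial genes, 32 fell (median log2 fold change -4.95, camera adjusted p = 2.26e-22, adjusted p = 0.183 with an estimated correlation). Cldn5, a tight junction gene of vessel walls, went from 316 ± 28.5 to 1.91 ± 0.749 FPKM (log2 fold change -6.80 ± 0.28, limma adjusted p = 3.01e-08). Cdh5, the gene of VE-cadherin, which joins endothelial cells, went from 457 ± 29.6 to 4.31 ± 2.07 FPKM, and Kdr, the gene of the VEGF receptor, from 214 ± 28.4 to 1.41 ± 0.385 FPKM. Of 32 arterial and Notch pathway genes, 3 rose, 23 fell and 6 did not pass (median log2 fold change -1.61, camera adjusted p = 2.86e-05, adjusted p = 0.302 with an estimated correlation). Among those that fell was Gja5, a connexin of arterial endothelium, from 33.8 ± 9.25 to 0.728 ± 0.281 FPKM. Stromal and mesenchymal genes fell too, 24 of 25 (median log2 fold change -3.50, camera adjusted p = 4.43e-12, adjusted p = 0.294 with an estimated correlation). The matrix gene Bgn went from 103 ± 6.41 to 1.29 ± 0.612 FPKM. Imprinted genes, expressed from 1 parental copy and often fetal growth regulators, gave 12 that fell and 1 that rose of 16 (median log2 fold change -3.37, camera adjusted p = 2.13e-06, adjusted p = 0.266 with an estimated correlation). The imprinted gene Mest had the largest fall of the named genes, from 1559 ± 122 to 8.03 ± 0.551 FPKM (log2 fold change -7.43 ± 0.33, adjusted p = 4.04e-08), and Plagl1, which switches on other imprinted genes, went from 312 ± 75 to 5.34 ± 1.67 FPKM. Of 11 fetal genes, 1 rose, 6 fell and 4 did not pass (median log2 fold change -0.86, camera adjusted p = 0.0579, adjusted p = 0.519 with an estimated correlation), although camera gave an adjusted p of 0.0447 without ex-HSC replicate 3 and 0.0338 without either FL-HSC library. The embryonic globin Hbb-y went from 588 ± 81.8 to 11.2 ± 1.99 FPKM, and the chromatin protein gene Hmga1 rose from 206 ± 18.9 to 508 ± 122. For the endothelial, arterial and Notch, stromal, imprinted and fetal lists, counts adjusted over the list alone were the same.

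Stem cell genes split. Of 42 HSC genes, 7 rose, 16 fell and 19 did not pass (median log2 fold change -0.28, camera adjusted p = 0.594, adjusted p = 0.932 with an estimated correlation). Procr, which encodes the stem cell surface protein EPCR, fell from 121 ± 16.8 to 14.5 ± 9.05 FPKM, and Fgd5 fell from 59.4 ± 8.91 to 4.16 ± 2.62 FPKM. Lineage lists differed, and most of the granulocyte, mast cell and lymphoid markers tested rose. Of 19 granulocyte markers, 17 rose and 0 fell (median log2 fold change 3.30, camera adjusted p = 6.97e-14, adjusted p = 0.183 with an estimated correlation). In pre-HSC 6 of the 19 had a mean of at least 1 FPKM, against 18 in ex-HSC and 17 in FL-HSC. Most therefore had little room to fall in either comparison against pre-HSC. S100a8, which encodes a neutrophil calcium-binding protein, went from 1.24 ± 0.818 to 288 ± 81.3 FPKM (log2 fold change 7.05 ± 0.31, limma adjusted p = 3.75e-08). Of 16 mast cell and basophil markers, 15 rose and 0 fell (median log2 fold change 3.92, camera adjusted p = 4.40e-14, adjusted p = 0.266 with an estimated correlation). The mast cell carboxypeptidase gene Cpa3 went from 2.31 ± 2.96 to 828 ± 378 FPKM (log2 fold change 8.24 ± 0.50, adjusted p = 3.40e-07), and the chymase gene Cma1 stood at 1135, 527 and 554 FPKM against 0, 0 and 0.352 in pre-HSC. Of 25 lymphoid markers, 13 passed the filter for testing. Of these, 10 rose and 0 fell (median log2 fold change 2.58, camera adjusted p = 1.29e-08, adjusted p = 0.183 with an estimated correlation), such as Flt3, the receptor gene of the Flt3L in the medium, from 3.16 ± 0.512 to 72.5 ± 15.8 FPKM. In ex-HSC 12 of the 25 had a mean of at least 1 FPKM, against 7 in pre-HSC. Of 21 erythroid markers, 11 rose and 1 fell (median log2 fold change 0.83, camera adjusted p = 0.000188, adjusted p = 0.386 with an estimated correlation). The carbonic anhydrase gene Car2 went from 33.3 ± 3.43 to 172 ± 49.2 FPKM. Of 17 megakaryocyte markers, 7 rose and 2 fell (median log2 fold change 0.33, camera adjusted p = 0.0349, adjusted p = 0.516 with an estimated correlation), and with quantile normalization 10 rose and 1 fell, with a median of 0.80. For this list camera gave an adjusted p of 0.0502 without pre-HSC replicate 1 and 0.133 without ex-HSC replicate 2. The HSC, granulocyte, lymphoid, erythroid and megakaryocyte lists had the same counts adjusted over the list alone, while by that adjustment 16 mast cell genes rose and 0 fell.

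Among immune genes, more rose than fell in each list in ex-HSC, and many did not pass. Of 27 checkpoint and costimulatory genes, 14 rose, 5 fell and 8 did not pass (median log2 fold change 0.80, camera adjusted p = 0.000685, adjusted p = 0.412 with an estimated correlation). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, went from 1.17 ± 0.269 to 50.8 ± 33.3 FPKM (log2 fold change 4.39 ± 0.38, limma adjusted p = 4.51e-06), while the immune regulator gene Cd200 fell from 20.6 ± 1.12 to 0.679 ± 0.560 FPKM. Of 25 antigen presentation genes, 18 rose and 1 fell (median log2 fold change 1.37, camera adjusted p = 1.56e-08, adjusted p = 0.386 with an estimated correlation). Cd74, the invariant chain of class II histocompatibility molecules, went from 3.20 ± 2.02 to 124 ± 28.6 FPKM (log2 fold change 4.98 ± 0.47, adjusted p = 9.19e-06). Of 46 interferon response genes, 17 rose, 1 fell and 28 did not pass (median log2 fold change 0.55, camera adjusted p = 9.67e-06, adjusted p = 0.590 with an estimated correlation). Isg20, an antiviral exonuclease gene, went from 1.74 ± 0.743 to 14.1 ± 3.69 FPKM. Of 41 inflammatory signalling genes, 13 rose, 5 fell and 23 did not pass (median log2 fold change 0.44, camera adjusted p = 0.00421, adjusted p = 0.590 with an estimated correlation), but without pre-HSC replicate 2 the median was 0.174 and the camera adjusted p 0.0643. Csf2rb, the shared receptor chain for IL-3, which was in the medium, rose from 5.74 ± 2.35 to 143 ± 82 FPKM, a value uncertain because its copy Csf2rb2 shares sequence with it. Of 18 cytokine feedback genes, 8 rose and 4 fell (median log2 fold change 0.38, camera adjusted p = 0.0242, adjusted p = 0.590 with an estimated correlation), and with quantile normalization 12 rose and 3 fell, with a median of 0.76. The list holds Socs, Pim, Spry, Dusp and Etv genes, among others. Socs2 went from 3.11 ± 0.488 to 49.6 ± 20.2 FPKM. Adjusted over the list alone, the counts were the same for the interferon, inflammatory and cytokine feedback lists. By that adjustment, 17 checkpoint genes rose and 5 fell and 20 antigen presentation genes rose and 1 fell.

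Metabolic genes rose in part, and few proliferation genes changed in the FPKM as deposited. Of 25 ATF4 targets, which supply amino acids under stress, 17 rose and 1 fell (median log2 fold change 1.32, camera adjusted p = 3.57e-09, adjusted p = 0.266 with an estimated correlation). The stress gene Chac1 went from 0.793 ± 0.371 to 26.5 ± 5.94 FPKM and the serine synthesis gene Phgdh from 49.2 ± 2.91 to 222 ± 36.7 FPKM. Of 24 glycolysis genes, 14 rose and 1 fell (median log2 fold change 0.77, camera adjusted p = 9.67e-06, adjusted p = 0.519 with an estimated correlation). The glucose transporter gene Slc2a3 went from 11.9 ± 1.34 to 51.8 ± 13.3 FPKM. Of 40 oxidative phosphorylation genes, 15 rose and 0 fell (median log2 fold change 0.43, camera adjusted p = 2.13e-06, adjusted p = 0.590 with an estimated correlation). Of 22 cholesterol synthesis genes, 6 rose and 2 fell (median log2 fold change 0.30, camera adjusted p = 0.0207, adjusted p = 0.590 with an estimated correlation). Fdps went from 67 ± 0.114 to 150.1 ± 12.1 FPKM. Of 36 S phase genes, 6 rose and 0 fell (median log2 fold change 0.24, camera adjusted p = 0.00557, adjusted p = 0.590 with an estimated correlation). With median-of-ratios scaling 18 S phase genes rose, while 1 rose without pre-HSC replicate 1 and 13 without ex-HSC replicate 2, so this count depended on scaling and on single libraries. The replication factor gene Rfc2 went from 69.1 ± 3.17 to 117 ± 20.2 FPKM. Of 41 G2/M genes, 2 rose and 6 fell (median log2 fold change -0.22, camera adjusted p = 0.594, adjusted p = 0.932 with an estimated correlation), and of 16 cell cycle inhibitors, 4 rose and 2 fell. For the inhibitors the median (-0.10) and the mean (0.24) differed in sign, the median turned to 0.06 with median-of-ratios scaling and to 0.19 with quantile normalization, and camera leaned up with an adjusted p of 0.298 and 0.790 with an estimated correlation. Among them, the p53 target Cdkn1a rose from 22.2 ± 12.9 to 122.9 ± 22.8 FPKM. For the glycolysis and cell cycle inhibitor lists, counts adjusted over the list alone were the same, while by that adjustment 21 ATF4 genes rose and 1 fell, 12 oxidative phosphorylation genes rose and 0 fell, 5 cholesterol genes rose and 0 fell, 0 S phase genes rose and 0 fell and 0 G2/M genes rose and 3 fell.

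Other lists gave mixed directions in ex-HSC with all libraries. Of 25 immediate early genes, which respond within minutes to signals, 6 rose, 5 fell and 14 did not pass (median log2 fold change 0.10, camera adjusted p = 0.144, adjusted p = 0.790 with an estimated correlation), but without ex-HSC replicate 2 the median was 0.710 and the camera adjusted p 0.0462. Ier3 rose from 29.4 ± 11.4 to 133 ± 65.7 FPKM, and the transcription factor gene Klf4 fell from 43.5 ± 3.26 to 10.9 ± 8.49. Of 24 adhesion and homing genes, 9 rose and 10 fell, with a median of -0.31, a mean of 0.11 and a camera direction of up (adjusted p = 0.578, adjusted p = 0.875 with an estimated correlation). The integrin gene Itgb7 rose from 0.879 ± 0.198 to 64.3 ± 17.4 FPKM and Cdh2, the gene of N-cadherin, fell from 20.1 ± 3.15 to 0.917 ± 0.154. Of 24 macrophage and monocyte markers, 5 rose and 8 fell, with a median of -0.83, a mean of -0.64 and a camera direction of up (adjusted p = 0.920, adjusted p = 0.981 with an estimated correlation). These markers differed widely between pre-HSC libraries, where the mannose receptor gene Mrc1 was at 68.8, 22.9 and 104 FPKM, against 9.59, 5.27 and 4.68 in ex-HSC. Of 12 hepatocyte markers, 1 rose and 4 fell (median log2 fold change -0.73, camera adjusted p = 0.142, adjusted p = 0.590 with an estimated correlation). The keratin gene Krt8 went from 11.5 ± 4.19 to 1.15 ± 0.387 FPKM. The immediate early, adhesion and hepatocyte lists had the same counts adjusted over the list alone. By that adjustment, 5 macrophage genes rose and 9 fell.

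In total, 6050 of 13720 genes changed in ex-HSC against pre-HSC (limma, adjusted p under 0.05), of which 2154 rose and 3896 fell. With a log2 fold change of at least 1 in size, 1138 rose and 2558 fell. The median of all genes was -0.16 on the log2 scale, and with median-of-ratios scaling it was -0.02, with 3643 genes that rose and 3917 that fell. With quantile normalization 4280 rose and 3424 fell. In the FPKM as deposited, but without ex-HSC replicate 2, 3086 rose and 3488 fell and the median was -0.025, so the excess of falls depended on scaling and largely on that library. The 3 libraries of each group did not overlap for 7600 genes, 55.4% of those tested, where chance gives 10%. Besides the genes above, the 10 largest rises included the histidine decarboxylase gene Hdc, the serotonin synthesis gene Tph1, Stfa1, Cyp11a1, Gzmb, S100a9 and the tryptase gene Tpsb2. The 10 largest falls included Aplnr, Plvap, Emcn, S100a16, Hspg2 and the embryonic globin Hba-x. Culture, embryonic age and sorting differed together between the groups, so the comparison does not separate them.

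FL-HSCs, taken directly from the fetal liver, show which of these changes also occur without culture. Endothelial, stromal and imprinted genes were again low against pre-HSC, and granulocyte genes were high. Most erythroid and S phase genes rose, as did 21 of 42 HSC genes. Most immediate early genes and 21 of 41 inflammatory genes fell, in contrast to ex-HSC, and most mast cell genes did not pass.

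Vascular genes fell in FL-HSC as well. Of 32 endothelial genes, 32 fell (median log2 fold change -4.24, camera adjusted p = 2.36e-24, adjusted p = 0.254 with an estimated correlation). Kdr went from 214 ± 28.4 to 1.83 ± 0.508 FPKM (log2 fold change -6.25 ± 0.24, limma adjusted p = 6.03e-08), and Plvap, a gene of the diaphragms of small vessels, from 599 ± 20.2 to 7.54 ± 2.65 FPKM. Of 32 arterial and Notch pathway genes, 3 rose, 23 fell and 6 did not pass (median log2 fold change -1.60, camera adjusted p = 1.48e-08, adjusted p = 0.254 with an estimated correlation). The neuropilin gene Nrp1, a co-receptor for VEGF, went from 49.6 ± 2.61 to 0.794 ± 0.743 FPKM. Of 25 stromal genes, 25 fell (median log2 fold change -3.56, camera adjusted p = 9.45e-18, adjusted p = 0.254 with an estimated correlation). The collagen gene Col3a1 went from 87.4 ± 37.4 to 0.109 ± 0.144 FPKM. Of 16 imprinted genes, 0 rose and 13 fell (median log2 fold change -2.96, camera adjusted p = 2.61e-08, adjusted p = 0.254 with an estimated correlation). Mest went from 1559 ± 122 to 7.53 ± 6.16 FPKM (log2 fold change -7.73 ± 0.37, adjusted p = 1.32e-07) and the fetal growth factor gene Igf2 from 1546 ± 83.2 to 72.8 ± 23 FPKM. Of 11 fetal genes, 1 rose and 4 fell (median log2 fold change -0.41, camera adjusted p = 0.0457, adjusted p = 0.653 with an estimated correlation), but camera gave an adjusted p of 0.0519 without pre-HSC replicate 1 and 0.0658 without pre-HSC replicate 2. Adjusted over the list alone, the counts were the same for the endothelial, stromal, imprinted and fetal lists, while by that adjustment 4 arterial and Notch genes rose and 25 fell.

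More stem cell genes rose than fell. Of 42 HSC genes, 21 rose, 7 fell and 14 did not pass (median log2 fold change 0.64, camera adjusted p = 0.00751, adjusted p = 0.670 with an estimated correlation). Slamf1, the gene of the stem cell marker CD150, went from 0.652 ± 0.300 to 14.9 ± 2.69 FPKM (log2 fold change 3.27 ± 0.30, limma adjusted p = 1.03e-05). Of 21 erythroid markers, 17 rose and 1 fell (median log2 fold change 3.14, camera adjusted p = 2.38e-08, adjusted p = 0.254 with an estimated correlation). Klf1, a transcription factor gene of red cell development, went from 0.822 ± 0.0598 to 87 ± 28.8 FPKM (log2 fold change 5.55 ± 0.32, adjusted p = 3.84e-07). Of 19 granulocyte markers, 16 rose and 0 fell (median log2 fold change 2.89, camera adjusted p = 4.02e-08, adjusted p = 0.256 with an estimated correlation). S100a8 went from 1.24 ± 0.818 to 116 ± 17.6 FPKM, and Elane, the neutrophil elastase gene, was at 48.3 and 44.4 FPKM against 0.0675, 0.222 and 0 in pre-HSC. Of 17 megakaryocyte markers, 8 rose and 2 fell (median log2 fold change 0.72, camera adjusted p = 0.111, adjusted p = 0.670 with an estimated correlation), and camera gave an adjusted p of 0.0277 without FL-HSC replicate 2. Of 13 lymphoid markers, 7 rose and 1 fell (median log2 fold change 1.02, camera adjusted p = 0.0131, adjusted p = 0.527 with an estimated correlation), such as Ikzf1, the gene of Ikaros, from 13.9 ± 0.162 to 151 ± 34.9 FPKM. Of 16 mast cell markers, 5 rose and 0 fell (median log2 fold change 0.10, camera adjusted p = 0.206, adjusted p = 0.786 with an estimated correlation), the largest being the granule proteoglycan gene Srgn from 72.5 ± 19.3 to 421 ± 0.204 FPKM. For the HSC, erythroid, granulocyte and lymphoid lists, counts adjusted over the list alone were the same. By that adjustment, 8 megakaryocyte genes rose and 3 fell and 4 mast cell genes rose and 0 fell.

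Signal response lists differed in direction in FL-HSC. Of 25 immediate early genes, 21 fell and 1 rose (median log2 fold change -2.97, camera adjusted p = 2.61e-08, adjusted p = 0.527 with an estimated correlation). Fos, which encodes a subunit of the transcription factor AP-1, went from 138 ± 40.2 to 0.477 ± 0.373 FPKM (log2 fold change -6.54 ± 0.59, limma adjusted p = 9.44e-06), and Atf3 from 68.3 ± 34.3 to 0.409 ± 0.406 FPKM. Of 41 inflammatory signalling genes, 2 rose and 21 fell (median log2 fold change -0.97, camera adjusted p = 0.00266, adjusted p = 0.670 with an estimated correlation). The chemokine gene Ccl3 was at 63.7, 18.1 and 96.3 FPKM in pre-HSC and at 0 and 0.532 in FL-HSC. It varied between pre-HSC libraries like the macrophage gene Mrc1, at 68.8, 22.9 and 104 FPKM, and macrophage markers were low in FL-HSC too, so the falls of such genes were not separated from those of macrophage markers. Of 18 cytokine feedback genes, 3 rose and 5 fell (median log2 fold change -0.40, camera adjusted p = 0.200, adjusted p = 0.777 with an estimated correlation), with Socs3 down from 51.6 ± 6.69 to 1.48 ± 0.488 FPKM. Of 27 checkpoint genes, 6 rose and 8 fell (median log2 fold change -0.17, camera adjusted p = 0.197, adjusted p = 0.680 with an estimated correlation), and the median turned to 0.15 with quantile normalization. Tnfrsf14, the gene of the receptor HVEM, rose from 4.80 ± 1.14 to 85.7 ± 0.367 FPKM, and Cd276, the gene of B7-H3, fell from 35.2 ± 0.292 to 2.59 ± 0.154. Of 25 antigen presentation genes, 15 rose and 1 fell (median log2 fold change 1.16, camera adjusted p = 0.00683, adjusted p = 0.670 with an estimated correlation). The immunoproteasome gene Psmb8 went from 16.5 ± 12.2 to 104 ± 21.7 FPKM. Of 46 interferon response genes, 7 rose and 4 fell, with a median of -0.02, or 0.18 with quantile normalization, a mean of 0.06 and a camera direction of up (adjusted p = 0.805, adjusted p = 0.962 with an estimated correlation). The immediate early, cytokine feedback and checkpoint lists had the same counts adjusted over the list alone, while by that adjustment 3 inflammatory genes rose and 22 fell, 15 antigen presentation genes rose and 2 fell and 7 interferon genes rose and 3 fell.

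Proliferation and metabolism differed from pre-HSC in part. Of 36 S phase genes, 26 rose and 0 fell (median log2 fold change 0.80, camera adjusted p = 8.02e-07, adjusted p = 0.532 with an estimated correlation). The replicative helicase gene Mcm7 went from 81.2 ± 1.52 to 256 ± 22 FPKM (log2 fold change 1.64 ± 0.21, limma adjusted p = 0.000113). Of 41 G2/M genes, 2 rose and 0 fell (median log2 fold change 0.07, camera adjusted p = 0.716, adjusted p = 0.958 with an estimated correlation), and the median turned to -0.11 with median-of-ratios scaling and with quantile normalization. Of 16 cell cycle inhibitors, 3 rose and 9 fell (median log2 fold change -1.03, camera adjusted p = 0.0111, adjusted p = 0.667 with an estimated correlation). Btg2 went from 50.4 ± 7.07 to 5.10 ± 0.281 FPKM. Of 24 glycolysis genes, 12 rose and 2 fell (median log2 fold change 0.63, camera adjusted p = 0.00751, adjusted p = 0.670 with an estimated correlation), such as Hk1, the hexokinase gene, from 27.6 ± 0.724 to 184 ± 16.9 FPKM. Of 40 oxidative phosphorylation genes, 12 rose and 0 fell (median log2 fold change 0.41, camera adjusted p = 0.00266, adjusted p = 0.670 with an estimated correlation), but without FL-HSC replicate 1 1 gene rose, the median was 0.253 and the camera adjusted p 0.134. Of 22 cholesterol synthesis genes, 0 rose and 11 fell (median log2 fold change -0.65, camera adjusted p = 0.00293, adjusted p = 0.667 with an estimated correlation). Cyp51 went from 23 ± 3.25 to 8.32 ± 0.769 FPKM. Of 25 ATF4 targets, 10 rose and 2 fell (median log2 fold change 0.47, camera adjusted p = 0.0719, adjusted p = 0.670 with an estimated correlation), and camera gave an adjusted p of 0.0498 without pre-HSC replicate 3. Adjusted over the list alone, the counts were the same for the cell cycle inhibitor, oxidative phosphorylation and ATF4 lists. By that adjustment, 29 S phase genes rose and 0 fell, 1 G2/M gene rose and 0 fell, 13 glycolysis genes rose and 2 fell and 0 cholesterol genes rose and 14 fell.

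Markers of other cells and adhesion genes showed the following in FL-HSC. Of 24 macrophage markers, 1 rose and 10 fell (median log2 fold change -1.62, camera adjusted p = 0.00440, adjusted p = 0.670 with an estimated correlation), but without FL-HSC replicate 2 the median was -0.566 and the camera adjusted p 0.175. The fetal liver macrophage gene Cd5l, which is not in the list, was at 90.7 and 13.6 FPKM in the 2 FL-HSC libraries. Of 12 hepatocyte markers, 2 rose and 2 fell (median log2 fold change 0.39, camera adjusted p = 0.805, adjusted p = 0.958 with an estimated correlation), with Hnf4a, a liver transcription factor gene, up from 0.445 ± 0.238 to 6.42 ± 1.45 FPKM. Of 24 adhesion and homing genes, 9 rose and 12 fell (median log2 fold change -0.94, camera adjusted p = 0.0801, adjusted p = 0.670 with an estimated correlation), with the P-selectin ligand gene Selplg up from 6.73 ± 2.47 to 47.4 ± 0.276 FPKM. For the hepatocyte and adhesion lists, counts adjusted over the list alone were the same, while by that adjustment 1 macrophage gene rose and 11 fell.

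In total, 5947 of 13720 genes changed in FL-HSC against pre-HSC (limma, adjusted p under 0.05), of which 3147 rose and 2800 fell. With a log2 fold change of at least 1 in size, 1694 rose and 2137 fell. The median of all genes was 0.13 on the log2 scale, and with median-of-ratios scaling it was -0.02, with 3070 genes that rose and 3725 that fell. With quantile normalization 4227 rose and 3103 fell, so which direction was more frequent depended on scaling. It also depended on single libraries, with 2014 rises and 2196 falls without FL-HSC replicate 1, 2394 and 2521 without FL-HSC replicate 2, 2342 and 2371 without pre-HSC replicate 1, and 2357 and 2603 without pre-HSC replicate 2. The libraries did not overlap for 9351 genes, 68.2% of those tested, where chance gives 20%. The 10 largest rises included the pyruvate kinase gene Pklr, Ermap, Stfa1, Cited4, Gata1, S100a9 and Ctsg. The 10 largest falls included Aplnr, Hbb-bh1, Col15a1 and Stmn2. Embryonic age and tissue differed together between the groups, and the sort gates are not given, so the comparison does not separate these.

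Cultured and fetal liver cells were then set against each other. Culture, tissue, age and sorting differed together between them, so a difference cannot be assigned to any of these. Among called genes, those of the HSC, erythroid and S phase lists were mostly higher in FL-HSC. Those of the mast cell, immediate early, inflammatory, checkpoint and cholesterol synthesis lists were mostly higher in ex-HSC. Cd274 did not differ by more than the spread between libraries.

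Most genes of the HSC and erythroid lists were higher in FL-HSC. Of 42 HSC genes, 28 were higher and 4 lower in FL-HSC (median log2 fold change 1.37, camera adjusted p = 2.14e-05, adjusted p = 0.499 with an estimated correlation). Slamf1 stood at 14.9 ± 2.69 FPKM in FL-HSC and 0.713 ± 0.593 in ex-HSC (log2 fold change 3.26 ± 0.30, limma adjusted p = 3.50e-05), and the stem cell maintenance gene Prdm16 at 15.2 ± 6.03 and 0.961 ± 0.302 FPKM. Of 21 erythroid markers, 15 were higher and 1 lower (median log2 fold change 2.41, camera adjusted p = 7.67e-06, adjusted p = 0.303 with an estimated correlation). Klf1 stood at 87 ± 28.8 and 2.90 ± 1.57 FPKM. The sort gates are not given. Whether erythroid cells in the FL-HSC libraries gave these values, here and against pre-HSC, was not tested. Of 36 S phase genes, 15 were higher and 0 lower (median log2 fold change 0.59, camera adjusted p = 0.000655, adjusted p = 0.499 with an estimated correlation), and the median was 0.24 with median-of-ratios scaling and 0.35 with quantile normalization. The replication checkpoint gene Clspn stood at 30.3 ± 7.08 and 11.5 ± 0.838 FPKM. Of 32 endothelial genes, 14 were higher and 2 lower (median log2 fold change 0.68, camera adjusted p = 0.0381, adjusted p = 0.606 with an estimated correlation). Sox18 stood at 17.2 ± 0.847 and 1.66 ± 1.03 FPKM. For the endothelial list, camera gave an adjusted p of 0.0533 without ex-HSC replicate 1 and 0.114 without FL-HSC replicate 1. Of 32 arterial and Notch genes, 2 were higher and 9 lower (median log2 fold change -0.25, camera adjusted p = 0.00235, adjusted p = 0.424 with an estimated correlation). The Notch target Hes1 stood at 1.73 ± 0.973 and 27.4 ± 12.4 FPKM. Of 16 imprinted genes, 4 were higher and 3 lower, with a median of -0.28, a mean of 0.10 and a camera direction of down (adjusted p = 0.331, adjusted p = 0.744 with an estimated correlation), and Grb10, an imprinted growth inhibitor, stood at 132 ± 14.4 and 12.7 ± 4.94 FPKM. Of 11 fetal genes, 1 was higher and 0 lower (median log2 fold change 0.50, camera adjusted p = 0.923, adjusted p = 0.955 with an estimated correlation), and the median was 0.16 with median-of-ratios scaling and 0.14 with quantile normalization. The arterial and Notch, imprinted and fetal lists had the same counts adjusted over the list alone. By that adjustment, 31 HSC genes were higher and 5 lower, 16 erythroid genes were higher and 2 lower, 19 S phase genes were higher and 0 lower and 15 endothelial genes were higher and 3 lower.

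Most mast cell and immediate early genes were higher in ex-HSC. Of 16 mast cell markers, 14 were lower in FL-HSC and 0 higher (median log2 fold change -3.38, camera adjusted p = 2.87e-19, adjusted p = 0.303 with an estimated correlation). Cpa3 stood at 3.14 ± 0.432 FPKM in FL-HSC and 828 ± 378 in ex-HSC (log2 fold change -7.56 ± 0.56, limma adjusted p = 9.83e-06). Of 25 immediate early genes, 23 were lower and 1 higher (median log2 fold change -2.83, camera adjusted p = 1.06e-18, adjusted p = 0.303 with an estimated correlation). Fosb stood at 0.0429 ± 0.00752 and 59.8 ± 46 FPKM. Of 41 inflammatory genes, 22 were lower and 3 higher (median log2 fold change -1.49, camera adjusted p = 5.11e-12, adjusted p = 0.303 with an estimated correlation). The chemokine gene Ccl5 stood at 0.693 ± 0.345 and 30.4 ± 4.91 FPKM. Of 18 cytokine feedback genes, 8 were lower and 0 higher (median log2 fold change -0.91, camera adjusted p = 9.01e-07, adjusted p = 0.347 with an estimated correlation). Cish stood at 5.0 ± 3.67 and 37.7 ± 11 FPKM. Of 27 checkpoint genes, 17 were lower and 2 higher (median log2 fold change -1.08, camera adjusted p = 1.62e-08, adjusted p = 0.303 with an estimated correlation). Havcr2, the gene of TIM-3, stood at 0.296 ± 0.0205 and 13 ± 4.30 FPKM. Of 46 interferon response genes, 9 were lower and 1 higher (median log2 fold change -0.59, camera adjusted p = 1.52e-07, adjusted p = 0.499 with an estimated correlation). The interferon brake Usp18 stood at 1.70 ± 0.418 and 8.17 ± 1.37 FPKM. Of 25 antigen presentation genes, 10 were lower and 0 higher (median log2 fold change -0.62, camera adjusted p = 4.47e-05, adjusted p = 0.499 with an estimated correlation). Cd74 stood at 9.29 ± 8.79 and 124 ± 28.6 FPKM. Adjusted over the list alone, the counts were the same for the immediate early, inflammatory and antigen presentation lists, while by that adjustment 0 mast cell genes were higher and 16 lower, 0 cytokine feedback genes were higher and 9 lower, 4 checkpoint genes were higher and 19 lower and 1 interferon gene was higher and 8 lower.

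Metabolic and cell cycle genes differed as follows. Of 22 cholesterol synthesis genes, 13 were lower in FL-HSC and 0 higher (median log2 fold change -0.80, camera adjusted p = 4.53e-09, adjusted p = 0.303 with an estimated correlation). Cyp51 stood at 8.32 ± 0.769 FPKM in FL-HSC and 52.7 ± 8.21 in ex-HSC (log2 fold change -2.52 ± 0.22, limma adjusted p = 2.30e-05). Of 25 ATF4 targets, 13 were lower and 1 higher (median log2 fold change -0.89, camera adjusted p = 2.44e-07, adjusted p = 0.303 with an estimated correlation). Trib3 stood at 3.65 ± 2.48 and 35.1 ± 14.3 FPKM. Of 16 cell cycle inhibitors, 8 were lower and 1 higher (median log2 fold change -0.70, camera adjusted p = 1.93e-05, adjusted p = 0.303 with an estimated correlation). Cdkn1a stood at 4.28 ± 2.53 and 122.9 ± 22.8 FPKM. Of 41 G2/M genes, 7 were higher and 0 lower (median log2 fold change 0.33, camera adjusted p = 0.365, adjusted p = 0.898 with an estimated correlation), and the median turned to -0.02 with median-of-ratios scaling. Of 24 glycolysis genes, 3 were higher and 6 lower (median log2 fold change -0.07, camera adjusted p = 0.0853, adjusted p = 0.744 with an estimated correlation), with a camera adjusted p of 0.0158 without ex-HSC replicate 2 and 0.0347 without FL-HSC replicate 1. Of 40 oxidative phosphorylation genes, 1 was higher and 4 lower, with a median of 0.05, a mean of 0.01 and a camera direction of down (adjusted p = 0.105, adjusted p = 0.830 with an estimated correlation). No gene was called lower without ex-HSC replicate 1 or ex-HSC replicate 3. Cox5a, Cycs and Ndufa1, among the lower genes, stood at -0.80, -0.68 and -0.70 with all FL-HSC and ex-HSC libraries. They stood at -0.81, -0.69 and -0.58 without ex-HSC replicate 1 and at -0.67, -0.59 and -0.66 without ex-HSC replicate 3. Without FL-HSC replicate 2 they stood at -0.43, -0.63 and -0.50. The list's lower calls thus depended on the library left out, while these folds stayed negative. The median turned to -0.31 with median-of-ratios scaling and to -0.08 with quantile normalization, and camera gave an adjusted p of 0.0227 without ex-HSC replicate 2 and 0.000335 without FL-HSC replicate 1. For the cell cycle inhibitor and glycolysis lists, counts adjusted over the list alone were the same. By that adjustment, 0 cholesterol genes were higher and 14 lower, 2 ATF4 genes were higher and 14 lower, 3 G2/M genes were higher and 0 lower and 1 oxidative phosphorylation gene was higher and 0 lower.

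Among lineage and adhesion lists, 5 of 19 granulocyte markers were higher in FL-HSC and 7 lower (median log2 fold change -0.57, camera adjusted p = 0.00361, adjusted p = 0.499 with an estimated correlation). The neutrophil granule gene Ngp stood at 3.17 ± 2.14 FPKM in FL-HSC and 31.1 ± 10.1 in ex-HSC. Of 13 lymphoid markers, 3 were higher and 8 lower (median log2 fold change -0.76, camera adjusted p = 2.90e-05, adjusted p = 0.303 with an estimated correlation). The interleukin receptor gene Il2rb stood at 0.0702 ± 0.0230 and 7.02 ± 0.179 FPKM. Of 17 megakaryocyte markers, 4 were higher and 3 lower, with a median of 0.34, a mean of 0.16 and a camera direction of down (adjusted p = 0.910, adjusted p = 0.955 with an estimated correlation). Of 24 macrophage markers, 1 was higher and 8 lower (median log2 fold change -0.59, camera adjusted p = 0.000130, adjusted p = 0.516 with an estimated correlation), but without FL-HSC replicate 2 the median was -0.190 and the camera adjusted p 0.153. Of 25 stromal genes, 3 were higher and 7 lower (median log2 fold change -0.43, camera adjusted p = 0.000571, adjusted p = 0.499 with an estimated correlation). Fstl1 stood at 23.1 ± 4.93 and 7.29 ± 0.503 FPKM. Of 12 hepatocyte markers, 7 were higher and 0 lower (median log2 fold change 1.23, camera adjusted p = 0.0727, adjusted p = 0.516 with an estimated correlation), and with median-of-ratios scaling 4 were higher. Camera gave this list an adjusted p of 0.0438 without pre-HSC replicate 2, 0.0361 without pre-HSC replicate 3 and 0.00148 without FL-HSC replicate 2. Of 24 adhesion and homing genes, 3 were higher and 10 lower (median log2 fold change -0.65, camera adjusted p = 4.19e-05, adjusted p = 0.303 with an estimated correlation). Itgb7 stood at 4.0 ± 0.317 and 64.3 ± 17.4 FPKM. The lymphoid, megakaryocyte, macrophage and stromal lists had the same counts adjusted over the list alone, while by that adjustment 5 granulocyte genes were higher and 10 lower, 8 hepatocyte genes were higher and 0 lower and 4 adhesion genes were higher and 11 lower.

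**Figure D4:**
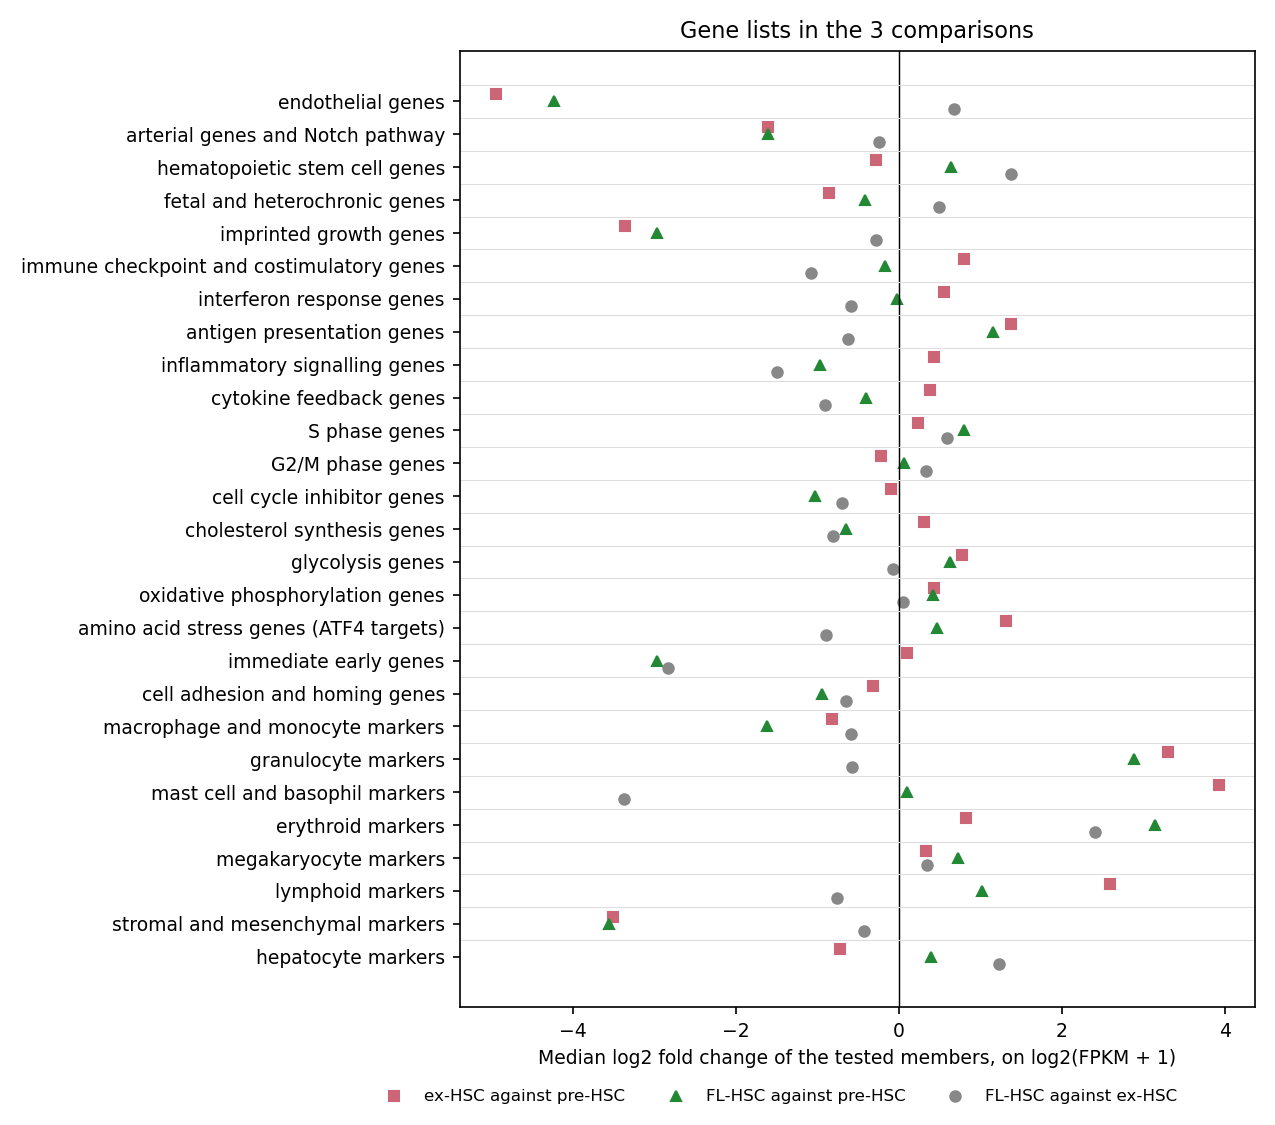
Median log2 fold change of each of 27 gene lists on the x axis, with the lists on the y axis and 1 symbol per comparison. Endothelial genes lie at -4.95 and -4.24 against pre-HSC, and mast cell markers at 3.92 in ex-HSC and 0.10 in FL-HSC, and these signs are the same under each scaling.

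In total, 4564 of 13720 genes differed between FL-HSC and ex-HSC (limma, adjusted p under 0.05), of which 3308 were higher and 1256 lower in FL-HSC. With a log2 fold change of at least 1 in size, 1804 were higher and 926 lower. The count was 2972 without FL-HSC replicate 1 and 2836 without FL-HSC replicate 2. The median of all genes was 0.27 on the log2 scale, and with median-of-ratios scaling it was -0.03, with 2482 higher and 2512 lower. With quantile normalization 2827 were higher and 2225 lower, so both the presence and the size of an excess of higher genes depended on scaling. The libraries did not overlap for 7737 genes, 56.4% of those tested, where chance gives 20%. The 10 genes highest in FL-HSC included Cd5l, Pklr, Atp1b2, Ermap, Cited4, Samd14 and the copy Tma7-ps, which shares sequence with its parent gene, so its value is uncertain. They also included Prmt3, listed at 0, 21.6 and 0 FPKM in ex-HSC, where a 0 can be a failed estimate, and its adjusted p was 0.0648 without ex-HSC replicate 1, 0.0578 without ex-HSC replicate 3, 0.0657 without FL-HSC replicate 1 and 0.0931 without FL-HSC replicate 2. The 10 lowest included Cma1, Tpsb2, Tph1, Gzmb, Hdc, Rgs1, Lilrb4 and Cyp11a1.

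Changes shared by ex-HSC and FL-HSC against pre-HSC were counted last, since ex-HSC came from culture and FL-HSC from the embryo. In both comparisons 1179 genes rose and 2256 fell, 3435 in all, and 198 moved in opposite directions. Independent lists of these sizes would share 494 and 795 genes. Of the shared genes, 855 that rose and 1741 that fell did not pass between FL-HSC and ex-HSC. Across all tested genes, which are not independent replicates, the correlation of the log2 fold changes was 0.690, against 0.450 in 100 simulated draws. In these draws all libraries, the pre-HSC ones included, were simulated as unchanged, and both groups shared the simulated pre-HSC libraries. The covariance of the log2 fold changes was 1.09 against 0.0574, a difference of 1.03. The same sign was seen for 69.7% of genes, against 64.8%. The draws gave 0 shared calls on average and at most 0. With no gene changed in them, few calls can pass the adjustment, so they do not show how many shared calls the controls bring. The 3 pre-HSC libraries cannot be split into parts of 2 libraries each, so part of the overlap may come from the shared controls.

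The genes with the largest shared rises included blood cell regulators and enzymes. Runx3, a transcription factor gene of blood lineages, stood at 0.594 ± 0.285 FPKM in pre-HSC, 51.6 ± 13.2 in ex-HSC and 22.6 ± 6.98 in FL-HSC. Ltb, which encodes lymphotoxin beta, stood at 7.48 ± 1.16, 112 ± 26.5 and 113 ± 7.07, the potassium channel gene Kcnn4 at 3.92 ± 1.16, 60.4 ± 12.4 and 63.2 ± 11.6, and the protease gene Napsa at 0.444 ± 0.341, 61.2 ± 16.8 and 20.1 ± 3.63. S100a8, Elane, Stfa1, S100a9, Ctsg and Camp were the other named rises. Mest, Aplnr, Cldn5, Kdr, Plvap, Hbb-bh1, Mmrn2, Cdh5, Plagl1 and Bgn were the named falls. Aplnr, the apelin receptor gene of developing vessels, stood at 322 ± 11 FPKM in pre-HSC, 0.911 ± 0.0666 in ex-HSC and 0.785 ± 0.380 in FL-HSC.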

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

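All tests in this part except the count of splits were chosen only after the results were seen. Ex-HSC replicate 2 stood out by signal in genes that no comparison used. Of the genes left out of the tests, 11410 were above 0 in it, against 2546 to 4877 in the other libraries.

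The signal in ex-HSC replicate 2 was wide and low. Of 1072 olfactory receptor genes, which blood cells do not use, 82.5% were above 0, 12.8 times the share of the next library, and of 405 vomeronasal receptor genes 80.7% were, against at most 10.9% elsewhere. The satellite repeat gene Gm10800, named after its values were seen, stood at 11986 FPKM there and 568 in ex-HSC replicate 3. Deeper sequencing would bring more genes above 0 but leave their summed FPKM about the same, while the olfactory receptor genes summed to 158.4 FPKM, 16.7 times the next library, where the others had 1.12 to 9.50. Named genes seen in this library alone had a 95th percentile of 0.489 FPKM. That value leaves out genes above 0 in any other library. It therefore cannot decide on RNA of another cell type, whose abundant genes may be above 0 in the others too. Genomic DNA left in the library may explain the signal, and which of the DNase methods it had is not stated.

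Mast cell and basophil genes were among the largest rises in ex-HSC, where 16 of 17 list genes had a mean of at least 1 FPKM, against 6 in pre-HSC, and 0 are in another list. All 15 members that rose, 100%, were highest in ex-HSC replicate 1, as were 43.1% of all 2154 genes that rose and 5.88% of granulocyte genes. Scaling would move both lineages alike, but the median log2 ratio of replicate 1 to the mean of replicates 2 and 3 was 1.09 for mast cell genes (quartiles 0.97 and 1.34) and -0.45 for granulocyte genes (-0.59 and -0.27). Mast cell or basophil lineage cells in the sort, at a share that differs between libraries, may explain this, with Cpa3 at 1264, 617 and 603 FPKM, and the sort gates, which might remove them, are not given. That the ex-HSCs themselves switch on these genes under IL-3 and SCF remains open and untested, since the libraries are pooled cells.

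Immediate early genes were low in FL-HSC and not in pre-HSC or ex-HSC. Scaling left the list's median at -3.09 against pre-HSC with median-of-ratios factors. Macrophage RNA in pre-HSC libraries would make these genes vary with the macrophage markers. Between pre-HSC replicates 3 and 2 the median log2 difference was 0.45 for the immediate early genes that fell (quartiles 0.15 and 0.83). It was 2.38 for macrophage markers (2.03 and 2.62) and 0.0084 for all genes tested (-0.19 and 0.24). Macrophage RNA is therefore unlikely as the whole cause, but it may account for part of the immediate early values. For inflammatory genes that fell, the median was 1.45 (0.70 and 2.26), so macrophage RNA may account for part of them. Handling before the sort, such as dissociation, and the age and tissue of the cells differ with the groups and remain open and untested.

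For the number of genes changed in ex-HSC against pre-HSC, the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 6050 genes, the highest of the others gave 2, and 1 split of the 10 gave as many as the real one, which was the real one.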

How the results depend on the processing

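The scaling without ex-HSC replicate 2 and the treatment of isolated zeros as missing were chosen only after the data were seen. Of 7 main results, which are the counts of changed genes, Cd274 in each comparison and the shared count, 83 of 86 values under other alternatives and 52 of 56 with 1 library left out stayed on their side of the threshold or within 1.5 times the count. The exceptions were the counts with a minimum absolute log2 fold change of 1, 3696 in ex-HSC and 3831 in FL-HSC against pre-HSC and 2730 between FL-HSC and ex-HSC, which are stricter by construction, and in FL-HSC against ex-HSC the gene count, 2836 to 4421 with 1 library left out, and Cd274, -0.48 to 0.12. For the 366 named-gene results, 4322 of 4388 values under alternatives and 2833 of 2928 with 1 library left out kept direction and call. For the 81 list results these were 827 of 891 and 612 of 648. No list passed with an estimated correlation. All 57 calls were lost, and the 24 results that stayed had not been called with the preset correlation. A direction turned only where neither value passed a threshold, and the cause was not tested. List values below are medians, while the direction that turned is that of camera, so the sign may stand. Macrophage markers in ex-HSC against pre-HSC turned at -0.64 with no filter, -1.01 at 5 FPKM, -0.67 with median-of-ratios scaling, -0.54 with quantile normalization, -0.70 with array weights, -0.83 with the replicate block, -0.83 with 2 groups only and -0.83 without ex-HSC replicate 2 and with scaling (-1.50 to -0.21 with 1 library left out). Adhesion genes there turned at -0.31 with no filter and -0.048 with quantile normalization. Megakaryocyte markers in FL-HSC against ex-HSC turned at 0.34 with no filter, 0.081 with median-of-ratios scaling, 0.33 with array weights and 0.16 without ex-HSC replicate 2 and with scaling (0.22 to 0.72), imprinted genes at -0.28 with no filter, G2/M genes at -0.092 without ex-HSC replicate 2 and with scaling, fetal genes with 1 library left out (0.22 to 0.55) and oxidative phosphorylation genes likewise (-0.21 to 0.26). In FL-HSC against pre-HSC, hepatocyte markers turned at -0.061 at 5 FPKM and 0.39 with 2 groups only (-0.20 to 1.01), G2/M genes at -0.11 with median-of-ratios scaling, -0.11 with quantile normalization and -0.11 without ex-HSC replicate 2 and with scaling, interferon genes with 1 library left out (-0.11 to 0.28), Ly6a at -0.011 with median-of-ratios scaling, -0.0028 with array weights and -0.011 without ex-HSC replicate 2 and with scaling (-0.43 to 0.73), and Pdcd1 at 0.020 with quantile normalization (-0.095 to 0). Some list counts depended on scaling. In ex-HSC against pre-HSC, the genes that rose went with median-of-ratios scaling and with quantile normalization from 6 to 18 and 20 for S phase, from 6 to 13 and 14 for cholesterol synthesis, from 6 to 11 and 9 for immediate early genes, from 7 to 10 and 12 for HSC genes, from 17 to 25 and 30 for interferon response from 15 to 32 and 21 for oxidative phosphorylation, from 8 to 9 and 12 for cytokine feedback and from 7 to 7 and 10 for megakaryocyte markers. The falls went from 6 to 8 and 10 for G2/M and from 8 to 7 and 4 for macrophage markers. In FL-HSC against ex-HSC, the lower genes went from 9 to 24 and 20 for interferon response, from 6 to 12 and 11 for glycolysis, from 4 to 9 and 8 for oxidative phosphorylation and from 0 to 6 and 2 for G2/M. Lower cytokine feedback genes went from 8 to 12 and 12, and higher hepatocyte markers from 7 to 4 and 6. The G2/M genes that fell in FL-HSC against pre-HSC went from 0 to 6 and 5, and the interferon genes that rose from 7 to 7 and 11. List medians between FL-HSC and ex-HSC also moved with median-of-ratios scaling and with quantile normalization, for example from 0.59 to 0.24 and 0.35 for S phase, from 0.50 to 0.16 and 0.14 for fetal genes, and from 0.34 to 0.081 and 0.15 for megakaryocyte markers. Glycolysis went from -0.07 to -0.43 and -0.23, imprinted genes from -0.28 to -0.54 and -0.32, and endothelial genes from 0.68 to 0.45 and 0.49. In ex-HSC against pre-HSC, S phase went from 0.24 to 0.40 and 0.43, HSC genes from -0.28 to -0.13 and -0.25, and oxidative phosphorylation from 0.43 to 0.60 and 0.27. In ex-HSC against pre-HSC, with quantile normalization, the medians went from 0.38 to 0.76 for cytokine feedback, from 0.33 to 0.80 for megakaryocyte markers, from 0.80 to 1.23 for checkpoint, from 0.44 to 0.71 for inflammatory and from 0.55 to 0.94 for interferon genes. In FL-HSC against pre-HSC, oxidative phosphorylation went from 0.41 to 0.23 and 0.20. With 1 library left out, list counts that moved by over 1.5 times and at least 3 genes were as follows. In ex-HSC against pre-HSC, rises were 6 cholesterol synthesis (4 to 11), 7 HSC (6 to 14), 6 immediate early (4 to 13), 17 interferon response (9 to 25), 15 oxidative phosphorylation (6 to 29) and 6 S phase (1 to 13), and falls were 6 G2/M (3 to 7), 5 immediate early (4 to 8), 5 inflammatory (4 to 10) and 8 macrophage (3 to 13). In FL-HSC against pre-HSC, rises were 15 antigen presentation (9 to 16), 2 G2/M (1 to 8), 2 inflammatory (1 to 5), 7 interferon response (4 to 14), 5 mast cell (2 to 5) and 12 oxidative phosphorylation (1 to 19), and falls were 11 cholesterol synthesis (7 to 13), 7 HSC (4 to 8), 4 interferon response (3 to 8) and 10 macrophage (4 to 19). In FL-HSC against ex-HSC, higher genes were 7 G2/M (2 to 9), 7 hepatocyte (4 to 9), 3 inflammatory (0 to 3) and 15 S phase (9 to 18), and lower genes were 10 antigen presentation (6 to 11), 9 arterial (4 to 11), 6 glycolysis (2 to 10), 7 granulocyte (4 to 9), 17 checkpoint (11 to 17), 9 interferon response (5 to 15), 8 macrophage (3 to 9), 4 oxidative phosphorylation (0 to 4) and 7 stromal (2 to 9). The replicate block gave 6146, 5891 and 4328 changed genes. No pairing by replicate number was seen, since deviations of same-numbered pre-HSC and ex-HSC libraries correlated at -0.10, -0.04 and 0.02. For same-numbered pre-HSC and FL-HSC libraries the values were -0.11 and 0.14. Such values cannot exclude a shared litter or day. Camera was not run with isolated zeros as missing, since it takes no missing values. With 1 FL-HSC library left, the lone library is assumed to vary like the other groups. Depth is unknown, so genes at or near 0 cannot be called absent.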

Other observations

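The gene families in this part were chosen only after values were seen, no test of a family as a set was run, and directions were checked with FPKM as deposited, median-of-ratios scaling and quantile normalization. Most of the Hox genes tested, which give cells their position along the body, fell in both later populations. Of 11 Hoxc and Hoxd genes tested, 11 fell in ex-HSC (median log2 fold change -1.58) and 11 in FL-HSC (-1.66), such as Hoxd8 from 14.2 ± 0.694 FPKM in pre-HSC to 0.333 ± 0.136 in ex-HSC and 0 and 0 in the FL-HSC libraries. Of 8 Hoxb genes, 8 fell in ex-HSC (-2.13) and 6 in FL-HSC (-1.46), and 5 were higher in FL-HSC than in ex-HSC. Of 11 Hoxa genes, 9 fell in ex-HSC (-1.70) and 6 in FL-HSC (-0.83), and 1 rose in FL-HSC with quantile normalization. Hoxa9, a gene of blood progenitors, did not pass in either, at 45.3 ± 4.42, 38.4 ± 12.5 and 63.7 ± 10.6 FPKM. The medians kept their signs under each scaling. Stromal markers fell in the same comparisons, 24 of 25 in ex-HSC (-3.50) and 25 of 25 in FL-HSC (-3.56), and whether the Hox values of pre-HSC come from stromal cells in those libraries was not tested.

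Counts in 5 other families were as follows. Of 16 Eph receptor and ephrin genes, 12 fell and 4 did not pass in ex-HSC (-1.85), where 2 rose with median-of-ratios scaling and with quantile normalization, and 13 fell and 1 rose in FL-HSC (-1.65). Ephb4, a receptor gene of veins, went from 132 ± 5.77 FPKM to 1.83 ± 0.669 in ex-HSC and 4.93 ± 0.140 in FL-HSC. Of 25 semaphorin and plexin genes, 17 fell, 2 rose and 6 did not pass in ex-HSC (-1.48) and likewise 17, 2 and 6 in FL-HSC (-1.21), such as Plxnd1 from 304 ± 27.2 to 9.39 ± 3.87 and 25.4 ± 0.427 FPKM. Of 10 protocadherins, 10 fell in ex-HSC (-2.38) and 9 in FL-HSC (-1.87). Of 78 mitochondrial ribosomal protein genes, 31 rose and 2 fell in ex-HSC (median 0.48) and 32 rose and 0 fell in FL-HSC (0.53), and with median-of-ratios scaling 56 and 30 rose. Between FL-HSC and ex-HSC their median was 0.12, which turned to -0.24 with median-of-ratios scaling and to -0.16 with quantile normalization. Of 28 RNA polymerase subunit genes, 8 rose and 2 fell in ex-HSC (0.11) and 15 rose and 0 fell in FL-HSC (0.56), with the same signs under each scaling.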
